A study of Homo sapiens with 9 samples.

How the data were processed

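RNA was depleted of ribosomal RNA and sequenced as paired reads on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, base calls were turned into reads with bcl2fastq, reads were aligned to the human genome GRCh38 with STAR, and featureCounts from the Subread package counted them per gene. The counting setting for strand, the annotation release and other settings of these steps are not given in the sources used here. The count values are the gene counts as deposited by the authors, which were used without change. The CPM values deposited by the authors equal each count divided by the library's total of counts and scaled to a common total, to within 4.9e-11; no further scaling was applied by the authors to them. The CPM printed in the text for single genes are these deposited values.

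The deposited table has 60871 lines, of which 200 repeat the counts of 168 Ensembl genes under a further Entrez identifier. Those repeats were dropped, which left 60671 genes. Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which kept 21176. Library sizes were scaled by TMM, with factors from 0.995 to 1.01. The quasi-likelihood test of edgeR (robust glmQLFit, glmQLFTest) was fitted to all 9 libraries with 1 coefficient per group and no covariate, which leaves 6 residual degrees of freedom, and a gene is called when its Benjamini-Hochberg adjusted p is under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. The biological coefficient of variation was 4.73%. A 95% interval given for a target is a normal interval from its SE.

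Gene lists were tested with camera of limma 3.58.1 on the edgeR fit, with the preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of 1 comparison. Lists with fewer than 5 tested members were left out, which removed 1 of 32. Beside it, camera with an estimated correlation and fry were run. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes, and called 8 lists after PPFIBP1 siRNA, 20 after PLEKHA1 siRNA and 18 between the knockdowns. Of 1036 list symbols, 1031 matched the deposited symbols and 5 an older symbol. A member count adjusted over the list alone uses Benjamini-Hochberg within that list.

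The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule, each comparison with the control siRNA names the targeted gene, its paralog and the other target. It adds the 12 genes with the largest log2 fold change in each direction among called genes with a symbol, a mean of at least 5 CPM and all 3 knockdown libraries on 1 side of all 3 controls, a separation that chance gives in 10% of genes. Pseudogenes and small RNAs are not named. The direct and the shared comparison name 6 genes in each direction, and a gene list up to 4 members with the smallest adjusted p. Positions and overlaps of genes come from GENCODE 29 on GRCh38, which is older than some of the deposited identifiers and holds 20892 of the tested genes. H3C2 and H3C3 have no position in it. Because the strand setting is not given, reads of a gene and of a gene that overlaps it cannot be told apart.

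Correlations and overlaps of the 2 knockdowns were set beside 20 simulations in which unchanged groups were compared with the same controls. Higher expressed genes are those with a mean log2 CPM over 2. For the words in 3' UTRs, 12506 genes with an annotated 3' UTR and a mean of at least 1 CPM were searched, and 2418 genes had none to search. Log2 fold changes were regressed on the presence of each of 16326 words of 7 bases, on the length and on the GC content of the 3' UTR, with Bonferroni adjustment. Coding regions were not searched, nor was the other strand of each siRNA considered, and the siRNA sequences are not given in the sources used here.

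The alternatives were DESeq2 1.42.0 median-of-ratios size factors, library size alone, no filter, a filter of at least 1 CPM in 3 libraries, a fit to the 2 groups compared, the replicate number as a block, limma-voom, limma-trend on log2(CPM + 1) and log2(CPM + 0.1), and leaving out each library in turn. Chosen after seeing the data were thinning all libraries to the smallest total, removing each library's trend with GC content and gene length, and leaving the targeted gene out of its partner list. R 4.3.3 ran the tests, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 the searches of words and the plots.

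The labels do not say whether the replicates come from separate cultures or donors, so p-values measure only the spread between these libraries. Over the genes with enough counts, libraries of the same group differed by a chi-square per degree of freedom of 3.96 to 7.72, which is above counting noise, and libraries of different groups by 9.27 to 36.0. The first and second principal components held 20.5% and 13.3% of the variance. Depth allows small changes to be called in abundant genes and only large ones in scarce genes.

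The procedure was tried on simulated counts for 20656 genes with known fold changes. For simulated folds of 1.2, 1.3, 1.5 and 2, the test recovered 42.9%, 42.9%, 66.0% and 64.0% of changed genes in the PPFIBP1 comparison, 36.0%, 40.8%, 55.1% and 81.6% in the PLEKHA1 comparison and 37.4%, 40.8%, 62.6% and 75.8% in the direct comparison. False calls made up 4.46%, 6.84% and 5.60% of calls in the same order (5, 8 and 13 genes), against the 5% aimed for. Each recovery rests on 49 or 50 changed genes, or 98 or 99 in the direct comparison. Fewer genes were changed in the simulation than were called in the data. The adjusted p depends on that number, so these shares need not carry over to the real comparisons. A simulated list of 29 genes shifted 1.1-fold in the PLEKHA1 comparison gave a camera p of 1.6e-10, 3.5e-04 with an estimated correlation and 4.9e-06 with fry, and an unchanged list gave 0.205, 0.229 and 0.150. A simulated GC trend called 2302 unchanged genes before its removal and 7 after. The search of words found 0 words in unchanged values and ranked a planted word first (t = -7.66).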

Results

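RNA sequencing measured gene expression in primary human renal proximal tubule epithelial cells, called RPTECs in the labels, after treatment with small interfering RNAs (siRNAs). The 9 libraries form 3 groups of 3: cells given a non-targeting control siRNA (NT siRNA), an siRNA against PPFIBP1 (siPPFIBP1) or an siRNA against PLEKHA1 (siPLEKHA1). PPFIBP1 encodes a liprin-beta scaffold protein of the cell cortex. PLEKHA1 encodes a pleckstrin homology domain adaptor that binds the membrane lipid phosphatidylinositol 3,4-bisphosphate. Total counts per library were 45402598, 45283333 and 51455808 with the control siRNA, 50372163, 49304381 and 41476654 with the PPFIBP1 siRNA and 46072384, 42034769 and 50630789 with the PLEKHA1 siRNA. After the filter on low counts, 21176 genes were tested. FN1, the gene of the matrix protein fibronectin, took 4.51% ± 0.137 (SD, n = 3) of all counts in the control libraries, 4.28% ± 0.0915 after PPFIBP1 siRNA and 4.62% ± 0.134 after PLEKHA1 siRNA. Mitochondrial genes took 2.17% ± 0.0943, 1.87% ± 0.0181 and 1.95% ± 0.0838 of counts in the same order, with an exact two-sided permutation p of 0.1 for each knockdown, the smallest that 3 against 3 libraries allow.

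Each siRNA lowered its own target in all 3 of its libraries. PPFIBP1 (ENSG00000110841, chromosome 12, 27523431 to 27695564 on GRCh38) fell from 243 ± 4.31 CPM (counts scaled to a common library total, mean and SD, n = 3) with the control siRNA to 29.2 ± 1.33 CPM with its own siRNA, which left 12.1% of the control level (95% interval 11.5% to 12.7%). PLEKHA1 (ENSG00000107679, chromosome 10, 122374696 to 122442602 on GRCh38) fell from 96.3 ± 1.56 to 8.24 ± 0.713 CPM with its own siRNA, which left 8.53% (7.97% to 9.14%). PPFIBP1 also fell after PLEKHA1 siRNA, to 180 ± 3.25 CPM (log2 fold change -0.44, SE 0.031, edgeR adjusted p = 5.6e-18). PLEKHA1 after PPFIBP1 siRNA stood at 96.8 ± 2.25 CPM (log2 fold change 0.012, SE 0.039, adjusted p = 0.936). Their closest relatives were not called after PPFIBP1 siRNA: PPFIBP2 was scarce, with 1.94 CPM in controls, and PLEKHA2 stood at 70.3 CPM in controls and 69.9 CPM. After PLEKHA1 siRNA, PLEKHA2 rose slightly to 77.4 CPM (log2 fold change 0.14, adjusted p = 0.00710), a call that ended with limma-trend on log2(CPM + 1) and no filter (adjusted p = 0.0836, the highest of the alternatives).

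**Figure D1:**
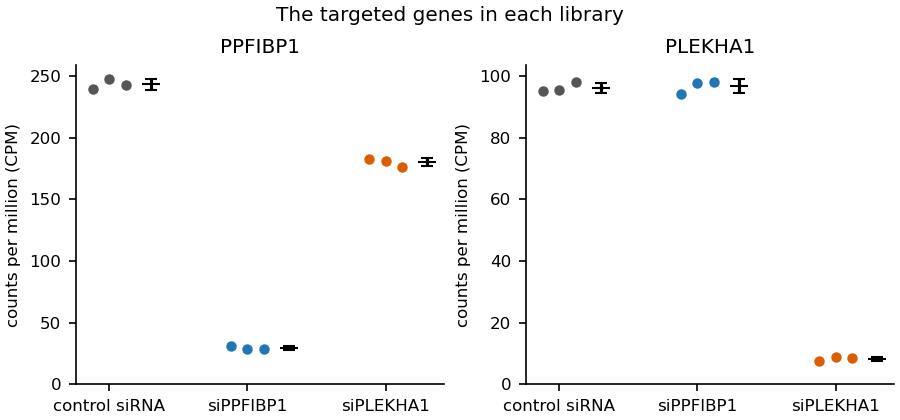
Expression of the 2 targeted genes in CPM (linear axis from 0), 1 point per library, with the group mean and SD (n = 3) as a black mark and bar. PPFIBP1 fell to 29.2 CPM with its own siRNA and stood at 180 CPM with the PLEKHA1 siRNA; PLEKHA1 fell to 8.24 CPM with its own siRNA.

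The first comparison asks which transcripts changed when PPFIBP1 was lowered. Cells given the PPFIBP1 siRNA had more mRNA of cholesterol synthesis enzymes and of the Argonaute and TNRC6 proteins that act in RNA silencing, and less mRNA from the mitochondrial genome, the last a list call lost with an estimated correlation (adjusted p = 0.118). Most changes were small. The test called 999 of 21176 genes, 559 higher and 440 lower, with a median absolute log2 fold change of 0.180 among the called genes. Changes of at least 2-fold were seen in 20 genes, 7 of them higher and 13 lower.

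Among genes with a mean of at least 5 CPM, the largest fall apart from the target was that of HSDL2, a peroxisomal dehydrogenase-like enzyme, from 41.6 ± 2.72 to 15.8 ± 1.06 CPM (log2 fold change -1.40, SE 0.056, edgeR adjusted p = 7.8e-29). GTPBP10, a GTPase of mitochondrial ribosome assembly, fell by 0.77 on the log2 scale, the salt-inducible kinase SIK1 by 0.74, and the glucose transporter SLC2A3 by 0.70. Among transcriptional regulators, HLF (-0.67), the SAGA complex subunit TADA2B (-0.63) and the chromatin protein MORF4L2 (-0.55) fell. UCHL5, a deubiquitinase of the proteasome (-0.65), RILPL2, a regulator of ciliary transport (-0.63), and G0S2, an inhibitor of fat breakdown (-0.56), were also lower. Of the 11 largest falls besides PPFIBP1, 7 carry the 7-base word GCACGTT in an annotated 3' untranslated region (UTR). Among them are HSDL2, GTPBP10, HLF, UCHL5, TADA2B and MORF4L2. Of all 12506 genes searched, 398 hold the word, and of the 12 largest rises 0 do. The word was picked from these same fold changes, so its count among the falls is no independent evidence. MORF4L2 has a close relative, MORF4L1, and sharing of reads between them was not tested.

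The largest rise among such genes was in PSKH1, which encodes a serine kinase, from 34.0 ± 0.896 to 54.4 ± 1.76 CPM (log2 fold change 0.68, SE 0.046, edgeR adjusted p = 3.5e-18). Cell-surface and matrix genes that rose were SRPX2, a secreted protein (0.48), S1PR2, a sphingosine 1-phosphate receptor (0.41), IL1RAP, a subunit of the interleukin 1 receptor (0.40), the metalloprotease ADAM19 (0.39) and the basement membrane protein FREM2 (0.39). TRIM9, a ubiquitin ligase (0.50), the membrane protein gene PLEKHB1 (0.46), the Argonaute gene AGO4 (0.43), the deubiquitinase YOD1 (0.40), the cholesterol enzyme MSMO1 (0.39) and the cyclin-dependent kinase inhibitor CDKN2B (0.39) completed the 12 largest rises. The call of S1PR2 was lost without NT siRNA replicate 1, NT siRNA replicate 3 or siPPFIBP1 replicate 3 (adjusted p = 0.0816, 0.139 and 0.156; 0.00502 to 0.209 over the alternatives), and also with limma-trend and no filter, and that of TRIM9 without NT siRNA replicate 2 (adjusted p = 0.0515; 0.00263 to 0.0515 over the alternatives).

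Among 31 gene lists fixed in advance, the camera test called 11 after PPFIBP1 siRNA, 7 of them up and 4 down, and 3 held when the correlation between genes was estimated. Of 34 cholesterol and fatty acid synthesis genes, 21 rose and 0 fell (24 and 2 adjusted over the list alone; camera adjusted p = 2.3e-20; adjusted p = 0.0298 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, rose from 82.3 to 106 CPM, and MSMO1, ACAT2 (0.33) and the lanosterol synthase LSS (0.21) rose too, although 69.7% of the exonic bases of ACAT2 overlap another gene. The RNA interference list had 6 of 14 genes higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 7.9e-11; adjusted p = 0.0298 with an estimated correlation). Its members TNRC6B (0.36), AGO2 (0.27), AGO4 and TNRC6A (0.22) rose. All 4 also rose after PLEKHA1 siRNA (0.28, 0.24, 0.40 and 0.13), and none of them was called between the knockdowns (edgeR adjusted p = 0.113, 0.666, 0.831 and 0.0523). The PPFIBP1 partner list, liprins and proteins of cortical microtubule attachment, was called down with 2 of 20 genes higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 2.3e-20; adjusted p = 0.0120 with an estimated correlation). That call rested on PPFIBP1 itself, since without the targeted gene the list gave adjusted p = 0.834 (2.5e-22 to 0.834 over the alternatives), and with limma-voom adjusted p = 0.131. The adhesion scaffold KANK2 fell (-0.23), while the microtubule-end protein CLASP2 (0.20) and the phosphatase PTPRF (0.11) rose. The call of CLASP2 was lost without NT siRNA replicate 1 (adjusted p = 0.0764; 0.00145 to 0.0917 over the alternatives), and also with limma-trend and no filter, and that of PTPRF without NT siRNA replicate 2 (adjusted p = 0.0693; 1.9e-04 to 0.0693 over the alternatives).

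The other 8 calls were lost with an estimated correlation. Of 13 mRNAs encoded by mitochondrial DNA, 9 fell (11 adjusted over the list alone; camera adjusted p = 2.2e-18, and adjusted p = 0.118 with an estimated correlation). MT-CO1, a subunit of cytochrome oxidase, fell from 6897 to 5728 CPM, and MT-ND4 (-0.21), MT-ATP6 (-0.16) and MT-CO3 (-0.22) fell, whereas 52 of 53 nuclear genes of oxidative phosphorylation were not called. The call of MT-CO3 was lost with limma-voom and both limma-trend offsets with the filter, and that of MT-ATP6 with limma-voom and with GC and length trends removed. Integrin and focal adhesion genes included 11 higher and 1 lower of 32 (13 and 1 adjusted over the list alone; camera adjusted p = 3.1e-06, and adjusted p = 0.192 with an estimated correlation). Rises were seen in the caveolins CAV1 (0.34) and CAV2 (0.20) and the integrin subunits ITGA3 (0.16) and ITGB8 (0.29). The YAP and TEAD target list held 5 higher and 1 lower of 26 (8 and 1 adjusted over the list alone; camera adjusted p = 3.4e-04, and adjusted p = 0.110 with an estimated correlation). In it the matricellular gene CCN2 (0.22) and CRIM1 (0.20) rose. TGF-beta and matrix genes, called up, split into 13 higher and 5 lower of 46 (20 and 7 adjusted over the list alone; camera adjusted p = 0.0175, and adjusted p = 0.470 with an estimated correlation). The collagen COL4A1 rose (0.19), while TGFBI (-0.16) and COL7A1 (-0.23) fell. The TGF-beta call was lost without NT siRNA replicate 1, NT siRNA replicate 3 or siPPFIBP1 replicate 1 (adjusted p = 0.0738, 0.0559 and 0.0989; 0.00718 to 0.470 over the alternatives), and also with the filter of at least 1 CPM or fry. NRF2 targets, which answer oxidative stress, had 8 higher and 2 lower of 33 (11 and 3 adjusted over the list alone; camera adjusted p = 5.3e-04, and adjusted p = 0.152 with an estimated correlation). NQO1 rose (0.17), and the transporter ABCC3 fell (-0.18), a call lost with limma-trend and no filter.

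Cytosolic ribosomal protein genes shifted up as a list with 4 higher and 0 lower of 68 (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.0e-07, and adjusted p = 0.470 with an estimated correlation). Fry did not call the list (fry adjusted p = 0.0974). The rise of its member RPL7A (0.088) was lost without NT siRNA replicate 1, NT siRNA replicate 2, NT siRNA replicate 3, siPPFIBP1 replicate 2 or siPPFIBP1 replicate 3 (adjusted p = 0.106, 0.0664, 0.198, 0.0851 and 0.194; 4.4e-04 to 0.198 over the alternatives), and also with no filter on low counts. The p53 target list was called down with 1 higher and 3 lower of 34 (1 and 3 adjusted over the list alone; camera adjusted p = 0.00893, and adjusted p = 0.192 with an estimated correlation). The stress cytokine GDF15 (-0.33), the death receptor TNFRSF10B (-0.25) and TP53INP1 (-0.31) fell. In the replication list, also called down, 1 of 40 genes was lower, the helicase subunit MCM3 (-0.33; 1 adjusted over the list alone; camera adjusted p = 0.0432, and adjusted p = 0.470 with an estimated correlation). The call of that list was lost without NT siRNA replicate 1, NT siRNA replicate 3, siPPFIBP1 replicate 2 or siPPFIBP1 replicate 3 (adjusted p = 0.203, 0.0559, 0.145 and 0.105; 0.00827 to 0.470 over the alternatives), and also with the filter of at least 1 CPM or fry. The lists of mitosis (camera adjusted p = 0.975) and interferon response genes (0.733) were not called. Of 47 proximal tubule genes, 2 rose and 4 fell, and that list was not called (camera adjusted p = 0.959). Marker lists of other cell types were not called after PPFIBP1 siRNA: fibroblast (1 higher and 1 lower of 10; camera adjusted p = 0.708), leukocyte (0.673) and distal nephron (0.673). Endothelial markers were not tested as a list, since 3 of 13 passed the filter on low counts.

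The count of called genes was lower whichever single library was left out, against 999 with all libraries. Without NT siRNA replicate 1, 2 or 3 it was 634, 555 and 701. Without siPPFIBP1 replicate 1, 2 or 3 it was 634, 653 and 801. A fit with fewer libraries has fewer degrees of freedom, so these falls need not point to particular libraries.

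The second comparison asks which transcripts changed when PLEKHA1 was lowered. Genes of cell division fell together: histones, DNA replication factors and mitosis genes were lower, and the cell cycle inhibitor CDKN1A was higher. As lists, genes of glycolysis and the hypoxia response and of the unfolded protein and integrated stress response were higher, and metallothioneins were lower. In all, 4241 of 21176 genes were called, 2062 higher and 2179 lower, with a median absolute log2 fold change of 0.226 among them. At least 2-fold changes were seen in 116 genes, 47 higher and 69 lower.

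HMOX1, the heme-degrading enzyme heme oxygenase 1, rose from 253 ± 17.3 to 571 ± 5.19 CPM (log2 fold change 1.17, SE 0.043, edgeR adjusted p = 1.1e-11). IGFBP3, which binds insulin-like growth factors in the extracellular space, rose from 55.1 ± 1.96 to 120 ± 1.54 CPM (log2 fold change 1.12, SE 0.037, adjusted p = 1.2e-33). The hormone gene SST, which encodes somatostatin, doubled from 11.3 to 22.6 CPM. Transport and metabolism genes among the largest rises were the glycine transporter SLC6A9 (1.00) and the N-acetylaspartate synthase NAT8L (0.86). RASSF10 (0.90), the basement membrane protein nidogen 2 gene NID2 (0.89), PIANP (0.87), the kinase PSKH1 (0.83), the homeobox factor MEIS3 (0.75) and PLEKHB1 (0.67) were also among the 12 largest rises among genes with a mean of at least 5 CPM. Of NID2's exonic bases, 30.0% overlap another gene.

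SLC2A1, the main glucose transporter of many cells, fell from 236 ± 7.27 to 105 ± 3.08 CPM (log2 fold change -1.17, SE 0.030, edgeR adjusted p = 2.0e-39). The trafficking GTPase RAB14 fell from 80.0 to 37.3 CPM, and the ETS family transcription factors ETS1 (-0.99) and ELK3 (-0.94) fell, as did the collagenase MMP1 (-0.97). LONRF1, a RING finger protein (-1.11), COMMD2 (-1.01), the translation factor EIF5A2 (-0.93), SHCBP1, which acts in dividing cells (-0.92), RPL26L1, a ribosomal protein paralog (-1.09), and the metallothionein MT1M (-0.96) were lower too. RPL26L1 and MT1M have close relatives in the genome, so reads can be split between copies. The word TGAACTA stands in the annotated 3' UTRs of SLC2A1, RAB14 and EIF5A2, 3 of these 11 genes. Of all 12506 genes searched, 1549 hold it. It stands in 0 of the 12 largest rises, though FREM2 (0.33) and AGO4 (0.40) hold it and rose. The word was picked from these same fold changes, so its count among the falls is no independent evidence.

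Camera called 17 of the 31 lists after PLEKHA1 siRNA, 7 up and 10 down, and 6 of them held with an estimated correlation. Of 43 replication-dependent histone genes, 42 fell and 0 rose (all 43 fell adjusted over the list alone; camera adjusted p = 2.7e-60; adjusted p = 0.00233 with an estimated correlation). The histone genes H3C2 fell from 54.4 to 32.6 CPM, H3C3 from 47.7 to 30.0, H1-5 from 38.5 to 22.9 and H2BC17 from 25.4 to 14.6, although histone genes have near-identical copies that can share reads. Mitosis genes fell in 41 of 45 cases and rose in 0 (43 fell adjusted over the list alone; camera adjusted p = 8.9e-40; adjusted p = 0.0178 with an estimated correlation). The proliferation marker MKI67 (-0.80), the cytokinesis protein ANLN (-0.71), the spindle factor TPX2 (-0.58) and the kinetochore protein CENPF (-0.54) fell. Replication genes fell in 32 of 40 cases and rose in 0 (34 fell adjusted over the list alone; camera adjusted p = 5.2e-21; adjusted p = 0.0119 with an estimated correlation). The helicase subunits MCM5 (-0.60) and MCM4 (-0.44), the epigenetic regulator UHRF1 (-0.45) and the checkpoint protein CLSPN (-0.76) fell.

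Metallothioneins, small proteins that bind zinc and copper, fell in 7 of 9 cases and rose in 1 (1 and 7 adjusted over the list alone, as rises and falls; camera adjusted p = 5.3e-21; adjusted p = 0.00233 with an estimated correlation). MT2A fell from 3225 to 2324 CPM and MT1E from 672 to 398, with MT1F (-0.82) lower as well, all members of a family of near-identical genes. Hypoxia and glycolysis genes rose in 25 of 37 cases and fell in 1, the glucose transporter SLC2A1 (28 and 1 adjusted over the list alone; camera adjusted p = 3.6e-13; adjusted p = 0.0178 with an estimated correlation). The glycolytic enzyme PGK1 rose from 600 to 740 CPM, hexokinase 2 (HK2) from 94.7 to 119 and the carbonic anhydrase CA12 from 246 to 306. In the unfolded protein and integrated stress response list 21 of 44 genes rose and 3 fell (25 and 4 adjusted over the list alone; camera adjusted p = 3.9e-08; adjusted p = 0.0448 with an estimated correlation). Stanniocalcin 2 (STC2, 0.60), the transcription factor CEBPB (0.48), SESN2 (0.31) and the folate enzyme ALDH1L2 (0.43) rose.

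The remaining 11 calls were lost with an estimated correlation. Ribosomal protein genes rose in 44 of 68 cases by small amounts (49 and 0 adjusted over the list alone; median log2 fold change 0.093; camera adjusted p = 9.1e-11, and adjusted p = 0.240 with an estimated correlation). RPL13A (0.22) and RPL3 (0.15) are examples, and processed pseudogenes can share their reads. Lysosome and autophagy genes rose in 21 of 37 cases and fell in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 6.3e-08, and adjusted p = 0.0838 with an estimated correlation). The sialidase NEU1 (0.33), the glucosidase GAA (0.27) and the saposin precursor PSAP (0.18) rose. Mitochondrially encoded mRNAs fell in 11 of 13 cases (11 adjusted over the list alone; camera adjusted p = 1.0e-06, and adjusted p = 0.266 with an estimated correlation), as MT-CO1 did (-0.16). Cholesterol and fatty acid synthesis genes moved the other way from the PPFIBP1 knockdown. Of that list 16 of 34 fell and 4 rose (4 and 17 adjusted over the list alone, as rises and falls; camera adjusted p = 1.6e-06, and adjusted p = 0.138 with an estimated correlation). HMGCS1 fell from 82.3 to 52.2 CPM, and the sterol carrier STARD4 fell (-0.61). The annotated 3' UTR of HMGCS1 holds 1 copy of the word TGAACTA, and that of STARD4 holds 0. NRF2 targets rose in 9 of 33 cases and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 2.5e-05, and adjusted p = 0.0715 with an estimated correlation). HMOX1, the ferritin light chain FTL (0.32), the transketolase TKT (0.21) and EPHX1 (0.26) rose.

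Among p53 targets 10 of 34 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.00525, and adjusted p = 0.138 with an estimated correlation). CDKN1A rose from 463 to 663 CPM, and TNFRSF10B fell (-0.36). Interferon response genes fell in 5 of 39 cases (4 adjusted over the list alone; camera adjusted p = 0.00659, and adjusted p = 0.682 with an estimated correlation). Fry did not call that list (fry adjusted p = 0.183). The RNA sensor DDX58 (-0.42), IRF1 (-0.34) and DTX3L (-0.44) fell. Actin and SRF target genes split into 5 higher and 13 lower of 36 (6 and 14 adjusted over the list alone; camera adjusted p = 0.0499, and adjusted p = 0.466 with an estimated correlation). EGR1 (-0.42), the alpha-actinin ACTN1 (-0.22) and vinculin (VCL, -0.20) fell. Integrin and focal adhesion genes split into 5 higher and 12 lower of 32 (6 and 13 adjusted over the list alone; camera adjusted p = 0.0401, and adjusted p = 0.466 with an estimated correlation). LIMS1 (-0.41), ITGA6 (-0.34) and BCAR1 (-0.23) fell and tensin 1 (TNS1, 0.26) rose. The actin call was kept in 5 of 17 alternatives. It was lost without NT siRNA replicate 1, NT siRNA replicate 2, NT siRNA replicate 3, siPLEKHA1 replicate 1 or siPLEKHA1 replicate 3 (adjusted p = 0.145, 0.109, 0.0514, 0.168 and 0.137; 3.5e-04 to 0.466 over the alternatives), and also with median-of-ratios size factors, library size alone, the filter of at least 1 CPM, thinned libraries, the 2-group fit or partner lists tested without their targeted gene. The adhesion call, kept in 8 of 17, was lost without NT siRNA replicate 2, NT siRNA replicate 3, siPLEKHA1 replicate 1 or siPLEKHA1 replicate 3 (adjusted p = 0.149, 0.0706, 0.168 and 0.0591; 0.0137 to 0.466 over the alternatives), and also with the filter of at least 1 CPM, thinned libraries, limma-voom or the 2-group fit. The PLEKHA1 partner list, proteins of phosphatidylinositol 3,4-bisphosphate signalling, was called down with 4 higher and 3 lower of 22 (4 and 3 adjusted over the list alone; camera adjusted p = 0.00174, and adjusted p = 0.0838 with an estimated correlation). Its median log2 fold change was 0.073 and its mean -0.12, since PLEKHA1 is a member, and without the targeted gene the list was not called (adjusted p = 0.206; 2.3e-04 to 0.540 over the alternatives), nor with limma-voom (0.540). The catalytic subunit PIK3CA fell (-0.37), while AKT2 rose (0.12); the call of AKT2 was lost with GC and length trends removed. Of PIK3CA, 35.8% of the exonic bases overlap another gene, as do 28.0% of IRF1's. The annotated 3' UTR of PIK3CA holds 1 copy of TGAACTA.

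Markers of fibroblasts rose in 4 of 10 cases and fell in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0427, and adjusted p = 0.193 with an estimated correlation). Lumican (LUM, 0.25) and the surface protein THY1 (0.22) rose. The fibroblast call was lost without NT siRNA replicate 1, NT siRNA replicate 3 or siPLEKHA1 replicate 1 (adjusted p = 0.0679, 0.0547 and 0.0692; 0.00661 to 0.193 over the alternatives), and also with the filter of at least 1 CPM, thinned libraries or the 2-group fit. Of 6 leukocyte markers tested, 1 rose, and of 14 distal nephron markers 2 rose, in lists that neither camera nor fry called. Proximal tubule genes included 10 higher and 5 lower of 47, again without a call of the list (camera adjusted p = 0.583).

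**Figure D2:**
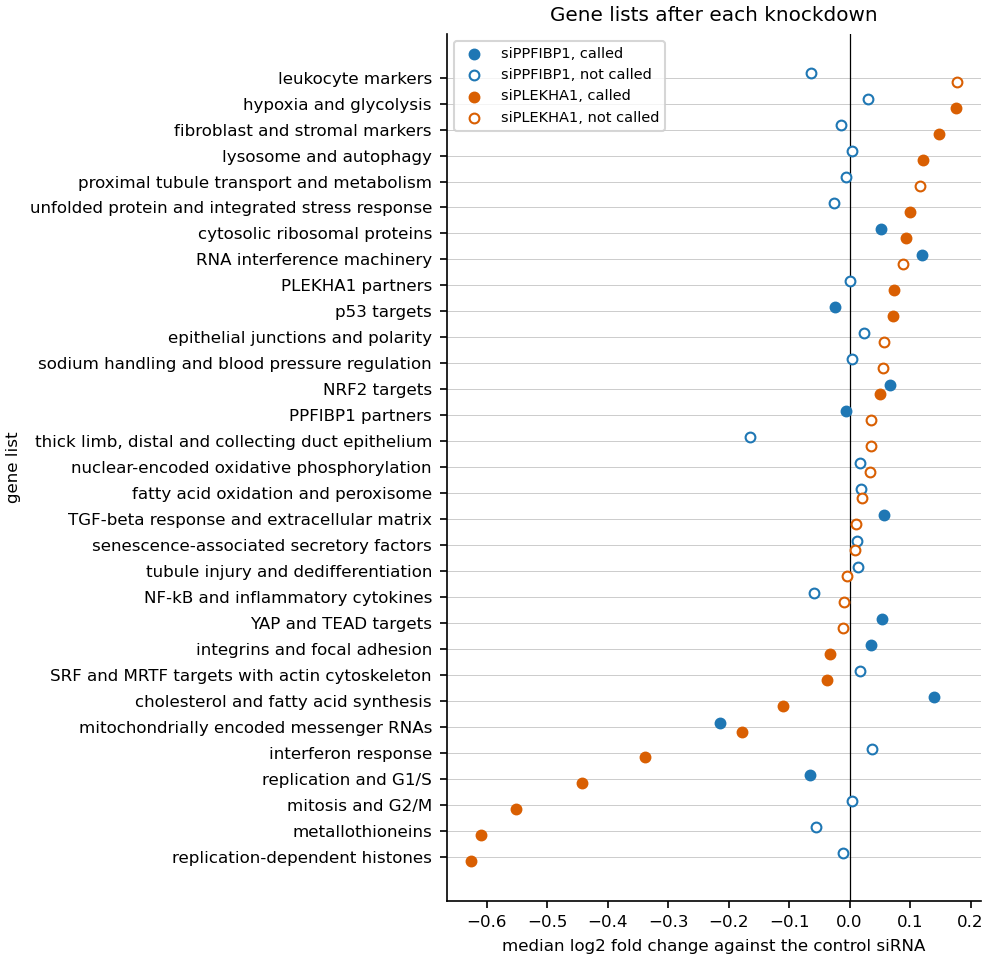
Median log2 fold change against the control siRNA (horizontal axis) of the tested members of 31 gene lists (vertical axis) after PPFIBP1 siRNA (blue) and PLEKHA1 siRNA (orange); filled points are lists called by camera with the preset correlation. The medians of histone, mitosis and replication genes after PLEKHA1 siRNA were -0.63, -0.55 and -0.44.

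The third comparison sets the 2 knockdowns against each other, with positive values for higher expression after PPFIBP1 siRNA. Cell division genes and cholesterol synthesis genes were higher after PPFIBP1 siRNA than after PLEKHA1 siRNA, and stress response, hypoxia and p53 target genes were lower. Of 21176 genes, 4636 differed, 2486 higher and 2150 lower after PPFIBP1 siRNA, 172 of them at least 2-fold. Besides PLEKHA1, the largest positive differences among genes with a mean of at least 5 CPM were those of LONRF1 (1.32), SLC2A1 (1.16), RAB14 (1.15), MMP1 (1.15) and the protease DDI2 (1.03). Besides PPFIBP1, the largest negative ones were those of HSDL2 (-1.54), HMOX1 (-1.18), SLC6A9 (-1.13), IGFBP3 (-1.12) and the acute phase gene SAA2 (-1.12). SAA2 has a close relative, SAA1, and sharing of reads between them was not tested.

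Camera called 17 lists in this comparison, 10 up and 7 down, and 9 held with an estimated correlation. Mitosis genes were higher after PPFIBP1 siRNA in 41 of 45 cases (41 and 0 adjusted over the list alone, as higher and lower; camera adjusted p = 2.3e-32, and adjusted p = 0.0220 with an estimated correlation), with ANLN at 0.80. Histones were higher in 41 of 43 (42 and 0 adjusted over the list alone, as higher and lower; camera adjusted p = 4.4e-47, and adjusted p = 0.00537 with an estimated correlation), with H3C2 at 0.79. Replication genes were higher in 28 of 40 (29 and 0 adjusted over the list alone, as higher and lower; camera adjusted p = 1.4e-12, and adjusted p = 0.0220 with an estimated correlation), with MCM5 at 0.59. Metallothioneins were higher in 7 of 9 cases (7 and 0 adjusted over the list alone, as higher and lower; camera adjusted p = 6.5e-14, and adjusted p = 0.00537 with an estimated correlation). Cholesterol and fatty acid synthesis genes were higher in 25 and lower in 1 of 34 cases (26 and 2 adjusted over the list alone, as higher and lower; camera adjusted p = 1.5e-22, and adjusted p = 0.0220 with an estimated correlation). HMGCS1 differed by 1.03. Stress response genes were lower in 23 and higher in 4 of 44 cases (4 and 25 adjusted over the list alone, as higher and lower; camera adjusted p = 4.7e-10, and adjusted p = 0.0220 with an estimated correlation), with STC2 at -0.80 and the stress protein NUPR1 at -0.75. Hypoxia and glycolysis genes were lower in 25 and higher in 4 of 37 cases (4 and 26 adjusted over the list alone, as higher and lower; camera adjusted p = 1.5e-11, and adjusted p = 0.0220 with an estimated correlation), with SLC2A3 at -0.85. The p53 targets were lower in 14 and higher in 4 of 34 (5 and 14 adjusted over the list alone, as higher and lower; camera adjusted p = 2.1e-05, and adjusted p = 0.0348 with an estimated correlation), with CDKN1A at -0.47. The ninth list was that of PPFIBP1 partners, with 5 higher and 7 lower of 20 (5 and 8 adjusted over the list alone, as higher and lower; camera adjusted p = 1.8e-07, and adjusted p = 0.0242 with an estimated correlation), among them the liprin PPFIA4 at -0.69. Without the targeted gene it was not called (adjusted p = 0.461; 1.4e-08 to 0.461 over the alternatives), nor with limma-voom (0.135).

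The other 8 list calls between the knockdowns were lost with an estimated correlation. Lysosome genes were lower after PPFIBP1 siRNA in 24 and higher in 2 of 37 cases (3 and 24 adjusted over the list alone, as higher and lower; camera adjusted p = 1.0e-06, and adjusted p = 0.102 with an estimated correlation), with the cholesterol transporter NPC1 at -0.23. Integrin and adhesion genes were higher in 17 and lower in 3 of 32 (18 and 3 adjusted over the list alone, as higher and lower; camera adjusted p = 2.1e-06, and adjusted p = 0.143 with an estimated correlation), with ITGA6 at 0.49 and ITGAV at 0.31. Ribosomal protein genes were lower in 18 and higher in 2 of 68 (3 and 20 adjusted over the list alone, as higher and lower; camera adjusted p = 0.00917, and adjusted p = 0.673 with an estimated correlation), a list that fry did not call (fry adjusted p = 0.0893). Actin and SRF targets were higher in 13 and lower in 4 of 36 (15 and 6 adjusted over the list alone, as higher and lower; camera adjusted p = 0.0102, and adjusted p = 0.367 with an estimated correlation), with the tropomyosin TPM4 at 0.29. The actin call was lost without siPLEKHA1 replicate 1 (adjusted p = 0.0612; 2.0e-05 to 0.367 over the alternatives), and also with the filter of at least 1 CPM. PLEKHA1 partners were higher in 5 and lower in 8 of 22 (5 and 8 adjusted over the list alone, as higher and lower; camera adjusted p = 0.0253, and adjusted p = 0.157 with an estimated correlation), where the test and the mean (0.097) were positive and the median (-0.053) negative. That call was lost without siPLEKHA1 replicate 1 (adjusted p = 0.0641; 0.00116 to 0.342 over the alternatives), and also with the filter of at least 1 CPM, limma-voom or partner lists tested without their targeted gene. Fibroblast markers were lower in 4 and higher in 1 of 10 (1 and 4 adjusted over the list alone, as higher and lower; camera adjusted p = 0.0334, and adjusted p = 0.157 with an estimated correlation), with THY1 at -0.45. The fibroblast call was lost without siPPFIBP1 replicate 1, siPPFIBP1 replicate 3 or siPLEKHA1 replicate 1 (adjusted p = 0.0541, 0.0589 and 0.0612; 0.00311 to 0.157 over the alternatives), and also with the filter of at least 1 CPM or limma-voom. Interferon response genes were higher in 5 and lower in 2 of 39 (5 and 2 adjusted over the list alone, as higher and lower; camera adjusted p = 0.0334, and adjusted p = 0.744 with an estimated correlation), with DDX58 at 0.39. The interferon call was lost without siPPFIBP1 replicate 3, siPLEKHA1 replicate 1 or siPLEKHA1 replicate 2 (adjusted p = 0.430, 0.0934 and 0.0990; 1.0e-04 to 0.744 over the alternatives), and also with the filter of at least 1 CPM or fry. RNA interference genes were higher in 4 of 14 (5 and 0 adjusted over the list alone, as higher and lower; camera adjusted p = 0.0453, and adjusted p = 0.357 with an estimated correlation), with the endonuclease DICER1 at 0.39. The RNA interference call was kept in 7 of 17 alternatives. It was lost without siPPFIBP1 replicate 2, siPPFIBP1 replicate 3 or siPLEKHA1 replicate 1 (adjusted p = 0.0691, 0.0827 and 0.171; 0.00691 to 0.357 over the alternatives), and also with median-of-ratios size factors, library size alone, the filter of at least 1 CPM, thinned libraries, the 2-group fit or partner lists tested without their targeted gene. Mitochondrially encoded mRNAs were not called between the knockdowns (camera adjusted p = 0.646).

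Changes common to both knockdowns were compared gene by gene. Both siRNAs were followed by higher PSKH1, PLEKHB1, AGO4, S1PR2, TRIM9 and ROBO1, an axon guidance receptor, and by lower RECK, an inhibitor of matrix metalloproteases, PPFIBP1, C1GALT1, an enzyme that builds O-glycans, the gasdermin GSDME, the kinase RPS6KA5 and the zinc finger gene ZNF678. PSKH1 rose to 54.4 and 60.6 CPM from 34.0, and RECK fell to 12.3 and 9.97 CPM from 18.0. GSDME fell by 0.36 and 0.30 on the log2 scale, and C1GALT1 by 0.34 and 0.44. In all, 531 genes were called in both comparisons: 205 were higher in both, 109 lower in both, and 217 moved in opposite directions, all 217 of which also differed between the knockdowns. Independent lists of the same sizes would share 54.4, 45.3 and 100 over all tested genes. Of the 531 genes, 522 were among the 11785 higher expressed genes, where the counts were 202, 104 and 216. Independent lists there would share 87.4, 70.3 and 159. Part of the contrast over all genes thus comes from calls falling mostly in higher expressed genes. Simulated unchanged groups set against the same controls shared at most 1, but since such groups hold almost no calls, that does not measure what the shared controls add to lists with real effects. Nor do independent lists, which leave the shared controls out.

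Of the 12 shared genes named, 5 lost a call when a single library was left out. After PPFIBP1 siRNA the call of ROBO1 was lost without NT siRNA replicate 2, NT siRNA replicate 3, siPPFIBP1 replicate 1 or siPPFIBP1 replicate 3 (adjusted p = 0.280, 0.0895, 0.190 and 0.0911; 0.0243 to 0.280 over the alternatives), and also with limma-trend and no filter, that of RPS6KA5 without NT siRNA replicate 2, siPPFIBP1 replicate 2 or siPPFIBP1 replicate 3 (adjusted p = 0.0776, 0.0698 and 0.0976; 0.00553 to 0.0976 over the alternatives), and also with limma-trend and no filter. ZNF678 lost its call without NT siRNA replicate 3 (adjusted p = 0.131; 0.00272 to 0.131 over the alternatives), and also with limma-trend and no filter. After PLEKHA1 siRNA the call of TRIM9 was lost without NT siRNA replicate 1, NT siRNA replicate 2 or siPLEKHA1 replicate 1 (adjusted p = 0.0728, 0.0880 and 0.129; 0.0180 to 0.129 over the alternatives), and also with limma-trend and no filter, and that of S1PR2 without siPLEKHA1 replicate 1 (adjusted p = 0.0515; 5.8e-04 to 0.0515 over the alternatives). RPS6KA5 lost its call there without NT siRNA replicate 2 or siPLEKHA1 replicate 1 (adjusted p = 0.0761 and 0.0652; 0.0106 to 0.0761 over the alternatives), and ZNF678 without NT siRNA replicate 3, siPLEKHA1 replicate 1 or siPLEKHA1 replicate 3 (adjusted p = 0.335, 0.0576 and 0.116; 0.0200 to 0.335 over the alternatives), and also with limma-trend and no filter or GC and length trends removed.

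The count of 314 genes that moved the same way was 203 without NT siRNA replicate 1, 164 without NT siRNA replicate 2 and 203 without siPPFIBP1 replicate 1, and part of the excess over independent lists may come from the 3 shared control libraries, which are too few to split. Across all genes, which are not independent replicates, the 2 sets of log2 fold changes had r = 0.348 and a covariance of 0.0390, against a median r of 0.501 and covariance of 0.0404 in 20 simulations of unchanged groups. Over the 11785 genes with higher expression, r was 0.142 against a simulated median of 0.508 (0.424 to 0.570). The covariance there was 0.00330 against a simulated median of 0.00322, a difference of 8.8e-05, and it lay within the simulated range of 0.00269 to 0.00429.

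**Figure D3:**
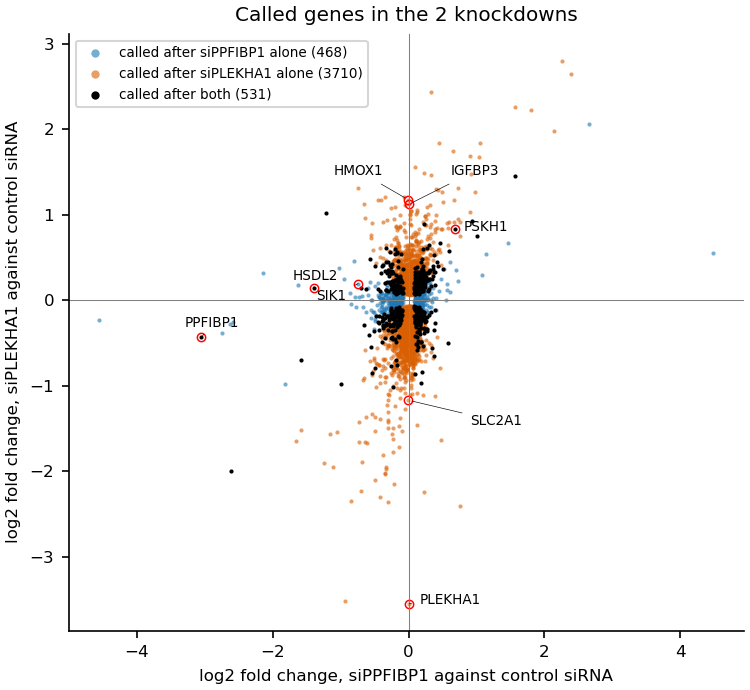
Log2 fold change against the control siRNA after PPFIBP1 siRNA (horizontal axis) and PLEKHA1 siRNA (vertical axis) for genes called in at least 1 comparison, 1 point per gene, with 8 named genes circled in red. 531 genes were called in both (black), 468 after PPFIBP1 siRNA alone (blue) and 3710 after PLEKHA1 siRNA alone (orange).

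Each of the 7-base words in 3' UTRs was also tested for its relation to the fold changes across 12506 genes. After PPFIBP1 siRNA the strongest word was GCACGTT: 398 genes with it had a median log2 fold change of -0.054, against 0.011 in genes without it. After PLEKHA1 siRNA it was TGAACTA: 1549 genes with it had a median of -0.062, against 0.012 without it. GCACGTT occurs once in annotated PPFIBP1 transcripts, in the coding region or the 5' UTR by transcript. TGAACTA occurs at 3 sites in annotated PLEKHA1 transcripts, 1 in a 5' UTR and 2 in transcripts with no coding region. The 3' UTR of PLEKHA1 holds 2 copies of GCACGTT, and PLEKHA1 was not called after PPFIBP1 siRNA (log2 fold change 0.012). TGAACTA occurs in annotated PPFIBP1 transcripts, though not in the 3' UTR searched, and PPFIBP1 fell after PLEKHA1 siRNA (log2 fold change -0.44). Whether that fall came from the siRNA seed was not tested.

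**Figure D4:**
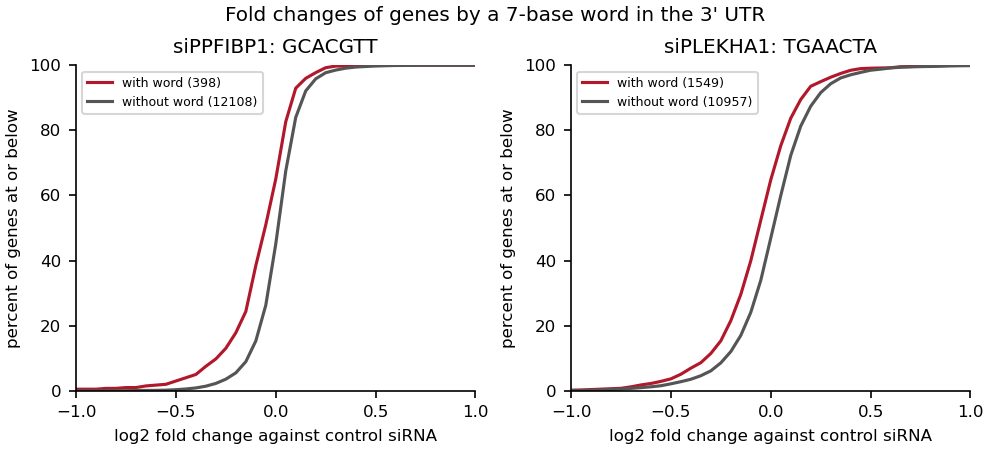
Cumulative percent of genes (vertical axis) at or below each log2 fold change against the control siRNA (horizontal axis), for genes with (red) and without (grey) GCACGTT in the 3' UTR after PPFIBP1 siRNA (left) and TGAACTA after PLEKHA1 siRNA (right). The medians with and without the word were -0.054 and 0.011 on the left and -0.062 and 0.012 on the right.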

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

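The alternatives of library thinning, removal of GC and length trends, and partner lists without their targeted gene were chosen after seeing the data. Of the values of main results under an alternative, 171 stayed on their side of the threshold or within the allowed range and 19 moved. With limma-trend on log2(CPM + 1) and no filter, which adds scarce genes to the adjustment and shrinks their fold changes, 384 genes were called after PPFIBP1 siRNA against 999, and 111 changed the same way in both knockdowns against 314. The correlation of the 2 sets of fold changes, 0.348 in the main test, was 0.485 with no filter, 0.225 with at least 1 CPM in 3 libraries, 0.235 with limma-trend on log2(CPM + 1) and 0.261 with that and no filter; these settings change how many scarce genes enter or how much they weigh. With an estimated correlation camera called 3, 6 and 9 lists after PPFIBP1 siRNA, after PLEKHA1 siRNA and between them, against 11, 17 and 17. With GC and length trends removed 1278 genes were called after PPFIBP1 siRNA, 4204 after PLEKHA1 siRNA and 4633 between them, and after thinning 908, 4164 and 4530. No scaling moved the share of higher among called genes by more than 10 points.

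Leaving out 1 library at a time gave 555 to 801 genes after PPFIBP1 siRNA, 3406 to 3729 after PLEKHA1 siRNA and 3832 to 4192 between the knockdowns. After PPFIBP1 siRNA the count was 634 without NT siRNA replicate 1, 555 without NT siRNA replicate 2, 634 without siPPFIBP1 replicate 1 and 653 without siPPFIBP1 replicate 2, and 530 to 712 of the 999 genes kept their call, with 0 changes of sign. The number that changed the same way ranged over 164 to 299, with 203 without NT siRNA replicate 1, 164 without NT siRNA replicate 2 and 203 without siPPFIBP1 replicate 1. A fit with fewer libraries has fewer degrees of freedom, and beyond that the cause was not tested. The correlation ranged over 0.315 to 0.495, the lists called over 9 to 11, 14 to 17 and 12 to 17, the log2 fold change of PPFIBP1 over -3.09 to -3.03 and that of PLEKHA1 over -3.60 to -3.47.

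For named genes, 4546 values under an alternative kept direction and call, 119 lost the call, 1 gained it and 3 reversed; 209 of 246 gene and comparison pairs kept both in every alternative, and 5 values could not be given because a filter removed the gene. The reversals are of values near 0 that were never called after PPFIBP1 siRNA: PLEKHA1 was -3.9e-04 without siPPFIBP1 replicate 3 (log2, -3.9e-04 to 0.0284 over the libraries left out), and PLEKHA2 was 3.6e-04 without NT siRNA replicate 1 and 0.0477 without siPPFIBP1 replicate 2 (-0.0370 to 0.0477); the cause was not tested. The replicate numbers did not pair the libraries: same-numbered libraries of different groups correlated in their deviations from the group means by -0.155 to 0.148, and 4 of 9 libraries correlated best with their own number. With the number as a replicate block the test called 965, 4174 and 4597 genes in the 3 comparisons and 11, 17 and 18 lists, and 301 genes changed the same way in both knockdowns.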

Other observations

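Gene groups of kidney function and injury that camera did not call still held single changes. Over all 21176 tested genes, 999 were called after PPFIBP1 siRNA and 4241 after PLEKHA1 siRNA. More member calls after PLEKHA1 siRNA than after PPFIBP1 siRNA therefore need not be particular to these groups. The called share was still well above that of all genes in some lists. After PLEKHA1 siRNA, only 12 of 30 tubule injury and 8 of 23 senescence-associated genes were not called. After PPFIBP1 siRNA, 28 of 36 sodium handling and 15 of 23 senescence-associated genes were not called, against 34 of 35 junction genes. Whether such shares exceed those of genes with similar expression was not tested. In the sodium handling and blood pressure list the numbers of called members were similar after both siRNAs. Sodium handling and blood pressure genes had 5 higher and 3 lower of 36 after PPFIBP1 siRNA (camera adjusted p = 0.975) and 3 higher and 6 lower of 36 after PLEKHA1 siRNA (0.519). Tubule injury and dedifferentiation genes had 3 higher and 2 lower of 30 (0.520) and 8 higher and 10 lower of 30 (0.184). Fry, which does not compare a list with other genes, called the tubule injury list after PLEKHA1 siRNA (fry adjusted p = 0.0239) and between the knockdowns (0.00574). Junction and polarity genes had 1 higher and 0 lower of 35 (0.321) and 10 higher and 6 lower of 35 (0.268). Senescence-associated secretory genes had 4 higher and 4 lower of 23 after PPFIBP1 siRNA (0.673) and 7 higher and 8 lower of 23 after PLEKHA1 siRNA (0.321), with IGFBP3 and CDKN1A among the higher members and MMP1 among the lower members of the second. NF-kB and inflammatory cytokine genes had 2 higher and 2 lower of 35 (0.644) and 3 higher and 9 lower of 35 (0.501).

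Genes of fatty acid oxidation and the peroxisome had 2 higher and 0 lower of 31 after PPFIBP1 siRNA (camera adjusted p = 0.278) and 4 higher and 0 lower of 31 after PLEKHA1 siRNA (0.118), and nuclear genes of oxidative phosphorylation 7 higher and 3 lower of 53 after PLEKHA1 siRNA (0.158). After PLEKHA1 siRNA the lists of TGF-beta and matrix (12 higher and 7 lower of 46), YAP and TEAD targets (7 higher and 5 lower of 26), RNA interference (6 higher and 3 lower of 14) and PPFIBP1 partners (4 higher and 6 lower of 20) were not called by camera. Of the lists in this paragraph, fry called fatty acid oxidation (fry adjusted p = 0.0289), YAP and TEAD targets (0.00552) and RNA interference (0.0419) after PLEKHA1 siRNA. After PPFIBP1 siRNA the lists that neither camera nor fry called also include histones (1 higher and 0 lower of 43), metallothioneins (0 higher and 1 lower of 9), hypoxia and glycolysis (6 higher and 5 lower of 37), stress response (2 higher and 6 lower of 44), lysosome and autophagy (0 higher and 2 lower of 37), actin and SRF targets (4 higher and 1 lower of 36) and PLEKHA1 partners (1 higher and 3 lower of 22). Between the knockdowns, proximal tubule genes had 5 higher and 10 lower of 47 and senescence-associated genes 10 higher and 10 lower of 23, without a call of either list by camera (adjusted p = 0.602 and 0.217); fry called the senescence list (fry adjusted p = 0.0321) and not the other (0.401). Small structural and other RNAs of the misc_RNA class took 2.40% ± 0.152 (SD, n = 3) of counts in the control libraries, 2.20% ± 0.0731 after PPFIBP1 siRNA and 1.77% ± 0.215 after PLEKHA1 siRNA.

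The tests of thinned libraries, of removed GC and length trends, of called genes with none of the words and of mitosis genes with none of the words were chosen after the results were seen. Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split gave the highest count in each comparison, alone (1 of 10 splits): 999 genes after PPFIBP1 siRNA against at most 3 in another split, 4241 after PLEKHA1 siRNA against 0 and 4636 between the knockdowns against 0. The other splits mix libraries given different siRNAs within a group, so differences between the siRNAs add to the spread within groups. Their low counts therefore do not measure how many genes chance alone would give.

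Part of the lower genes after each siRNA may come from binding of the siRNA seed to 3' UTRs of transcripts other than its target. The word GCACGTT marked lower genes after PPFIBP1 siRNA (regression t = -13.7) and TGAACTA lower genes after PLEKHA1 siRNA (t = -9.42), and both occur in transcripts of the targeted gene, TGAACTA only in a 5' UTR and in transcripts with no coding region; of all words tested, 43.6% and 59.7% occur in some part of those transcripts. Of the searched genes called lower, 35.5% after PPFIBP1 siRNA and 21.6% after PLEKHA1 siRNA hold none of the words past the threshold. For these genes, direct binding to the 3' UTR through those words is argued against. Other direct binding stays open, since shorter seed matches were not searched and the words were picked from the same fold changes. An effect through an unintended target upstream stays open too. Of the searched genes that were not called, 36.4% and 62.4% hold such a word. For the fall of mitosis genes after PLEKHA1 siRNA, 23 of 24 searched members with none of the words were called lower (95.8%). That argues against direct binding to these members through those words, but not against shorter seed matches or such an upstream effect. The 19 searched mitosis genes with a word had a median log2 fold change of -0.61, against -0.54 in those without. The labels name no second siRNA per target, so loss of the target, the untested biological explanation, and seed effects on unintended targets both stay open. Seed effects could act directly for genes with a word, such as HSDL2, SLC2A1, RAB14 and HMGCS1. For genes without a word they could act through other genes or shorter matches.

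Genes higher in both knockdowns than with the control siRNA could in part be genes that the control siRNA lowers. The word TTTTCCT marked genes with a higher mean of the 2 fold changes (regression t = 6.41), with a small coefficient of 0.018 on the log2 scale. CCCCTCC and CTCCTCT also passed the threshold, but unlike TTTTCCT (t = 5.87) they did not with the shares of dinucleotides in the regression (t = 2.83 and 4.04), and 56.0% of the searched genes that were not called hold a word too. Of the searched genes called higher in both, 24.4% hold none of the 3 words. For these genes, direct binding of the control siRNA to the 3' UTR through those words is argued against. Shorter seed matches and an effect through an upstream target stay open. A response of these cells to any active siRNA, such as the rise of AGO4, or to loss of either protein was not tested.

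More genes were called after PLEKHA1 siRNA than after PPFIBP1 siRNA, by a ratio of 4.25. Depth is argued against as the cause, because the ratio was 4.59 after all libraries were thinned to the smallest total. GC content and gene length are argued against as the whole cause, because the ratio was 3.29 once each library's trend with them was removed. The ratio fell because the count after PPFIBP1 siRNA rose from 999 to 1278. The count after PLEKHA1 siRNA hardly moved, from 4241 to 4204. Fold changes after PLEKHA1 siRNA nevertheless correlated with GC content across genes (r = 0.247), which are not independent replicates. Still open are a larger biological effect of lowering PLEKHA1, more unintended targets of that siRNA and differences in culture that the labels do not record.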
